A study of Arabidopsis thaliana with 109 samples.

How the data were processed

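The series holds 109 samples of light-grown Arabidopsis seedlings, per the labels: 29 RNA-seq libraries, used here through 3 tables, and 80 ChIP samples, of which only the 3 deposited lists of PIF7 binding events were used here. The H2A.Z and other chromatin samples were not analysed here. Per the submitters' processing notes, STAR 2.6.0c and RSEM 1.3.0 were used for RNA-seq and Bowtie2 2.1.0 for ChIP, on the build TAIR10. The tables hold the authors' TPM for 33602 gene models, with nuclear rRNA and organellar genes included, and every column has the same total. The deposited event lists give, per event, the authors' position, strength (by the column name, IP), fold over control and -log10 q, which the caller caps. All value columns were mapped to a sample (0 unmapped).

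TPM keeps no read depth, so depth per library and intervals from counts could not be given. Genes at 1 TPM or more number 18468 to 18981 per library in table I, 18098 to 19020 in II and 17714 to 19215 in III, and rRNA and organellar transcripts take 3.27 to 12.8%, 1.24 to 5.06% and 4.09 to 23.1% of TPM. The median standard error of a log2 change among genes of at least 5 TPM was 0.212 in table I and 0.102 in table II.

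Because the tables hold TPM, the count models planned could not be used, and limma 3.58.1 (R 4.3.3) with an expression trend was fitted to log2(TPM + 1), a pseudocount of 1, the alternative that the design names for normalized values. Genes at 0 in every library of a table were left out and no other filter was set. All groups of a table shared 1 fit, with no replicate block, since replicate numbers did not pair the libraries (median correlation of residuals of same-number libraries -0.009, -0.0575 and -0.0165). Tables were never fitted together. p-values were adjusted over genes (Benjamini-Hochberg) within each of 11 comparisons, and a gene is called at an adjusted p under 0.05. The procedure was tested on simulated data, with changed genes drawn from those above about 5 TPM. It recovered 41%, 91% and 19% of 2-fold changes and 75%, 99% and 79% of 4-fold changes in tables I, II and III, and called 6, 14 and 3 unchanged genes.

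The 20 gene lists (310 genes) were fixed before the files were opened: shade-induced regulators, auxin biosynthesis, Aux/IAA and GH3, SAUR, gibberellin, brassinosteroid, growth-regulating HLH factors, cytokinin, ethylene, cell wall loosening, phytochromes and PIFs, clock, light-harvesting antenna, photomorphogenesis, flavonoid, jasmonate, touch, heat shock, H2A.Z and its remodellers, and root markers. Each was tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons of a table. Alternatives were camera with an estimated correlation and fry.

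Genes named in the text follow a rule also fixed beforehand: the 10 raised and 10 lowered genes of largest change (mean TPM of at least 5, groups not overlapping; the rule said CPM), up to 4 members per list by smallest p, 10 fixed genes (PIF4, PIF5, PIF7, PIL1, ATHB2, HFR1, YUC8, IAA19, IAA29, XTH15), and genes of differing response. Not every gene of the rule is printed. Symbols come from a RefSeq gene table of TAIR10.1, which paired 32835 gene models.

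An event was assigned to the nearest of 27444 protein-coding genes within 3 kb of its span, or inside it. The design named start sites, but the table has no strand. Enrichment used Fisher's exact tests, adjusted over 18 tests. Overlap of lists means events within 100 bp, set against 100 random placements. No genome sequence was held, so the planned motif test was not run and the authors' k-mers are described. Genes near and not near events were compared by 100000 permutations within strata. Alternatives tried were the pseudocount, filters on low TPM, a 2-fold threshold (for counts, not for single genes), a replicate block, a fit to the compared groups alone, leaving out each library, other event distances and the events above the median strength of each list, and 2 scalings chosen after seeing the data (rRNA and organellar genes removed with TPM rescaled, and median centring). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for events and figures.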

Results

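Low red to far-red light (low R:FR) is the light signal of vegetation shade, and seedlings answer it with a fast change of transcription. 29 RNA-seq libraries from 3 expression tables and 3 lists of PIF7 binding events were compared. Table I holds wild type (Col-0) in white light, after 2 h of low R:FR, and after 2 h of low R:FR followed by 2 h of white light (recovery). Table II holds the pif457 line that carries PIF7-4xMYC, in white light and after 5, 10 and 30 min of low R:FR. Table III holds wild type and pif457 in white light and after 30 min. Groups have 3 libraries in tables I and II and 2 libraries in table III. Values are the authors' TPM as mean ± SD, first the group named first, and log2 changes are of TPM + 1. Genes are called raised or lowered at an adjusted p under 0.05 (limma). Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples. The fit also draws each gene's variance toward that of genes of like level, so p-values rest partly on other genes. A gene that did not pass is not shown to be unchanged. Titles of the RNA-seq libraries give no hour of harvest. If groups differ in it, light and hour cannot be told apart. In simulated data the test recovered 41%, 91% and 19% of 2-fold changes in tables I, II and III.

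The transcripts of PIF4, PIF5 and PIF7, after which pif457 is named, come first. PIF7 (AT5G61270) encodes a phytochrome-interacting bHLH factor. In the wild type of table III it stood at 28 and 25.4 TPM in white light and at 21.6 and 23.4 TPM after 30 min of low R:FR. In pif457 it stood at 1.24 and 0.84 TPM in white light and at 0.35 and 1.47 TPM after 30 min. Its relative PIF5 (AT3G59060) stood at 33.2 and 42.7 TPM, then 19.2 and 21.3 TPM in wild type. In pif457 its values were 2.71 and 4.03 TPM, then 1.6 and 2.45 TPM. PIF4 (AT2G43010) stood at 32.5 and 47.1 TPM, then 13.7 and 14.8 TPM in wild type. Its pif457 values were 11.9 and 11.3 TPM, then 3.12 and 6.36 TPM. A transcript level does not test whether the protein is lost. The line of table II carries the tagged PIF7. There PIF7 transcript stood at 126±8.71 TPM in white light, with PIF4 at 14.4±1.23 and PIF5 at 4.2±1.09 TPM.

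After 2 h of low R:FR the wild type carried far more transcript of shade regulators and of auxin genes than in white light. ATHB2 (AT4G16780, 140.2±8.44 against 7.06±2.03 TPM, log2 change 4.16, adjusted p = 9.03e-06), a homeodomain-leucine zipper gene of the shade response, rose. So did the bHLH genes PIL1 (AT2G46970, 39.5±3.83 against 0.327±0.283 TPM, log2 4.95) and HFR1 (AT1G02340, 48±1.02 against 6.33±1.06 TPM, log2 2.75) and the ATHB2 relative HAT2 (AT5G47370, 159±11.4 against 22.1±1.98 TPM, log2 2.8) (3 libraries each). The auxin-responsive repressor genes IAA29 (AT4G32280, 177±27 against 4.76±2.02 TPM, log2 change 5.0, adjusted p = 9.03e-06) and IAA19 (AT3G15540, 82±4.74 against 1.82±0.618 TPM, log2 4.9) rose. GH3.3 (AT2G23170, 113±5.04 against 6.53±0.741 TPM, log2 3.93) rose too, and encodes an auxin-conjugating enzyme. YUC8 (AT4G28720, 24±6.36 against 0.913±0.794 TPM, log2 3.79) and YUC9 (AT1G04180, 12.6±5.13 against 0.37±0.327 TPM, log2 3.28), which encode flavin monooxygenases of auxin synthesis, also rose. ACS8 (AT4G37770, 29.6±6.04 against 0.137±0.237 TPM, log2 4.75), an ethylene precursor synthase gene, rose with them. Transcript of the light receptor gene PHYB (AT2G18790, 46.8±4.08 against 20.5±3.53 TPM, log2 1.16) rose. PIF7 fell (16.2±4.48 against 52.6±1.71 TPM, log2 change -1.68, adjusted p = 0.00254) and so did PIF1 (AT2G20180, 28.1±2.42 against 50.9±2.09 TPM, log2 -0.84).

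In all, 314 genes rose and 186 fell at 2 h in 25331 tested, 197 and 70 of them by at least 2-fold. The largest rises, besides those above, were in FLP1 (AT4G31380, 4.76), AT3G21330 (4.09), AT5G02760 (3.91) and AT4G34770 (3.86). The largest falls were in AT5G62360 (-2.16), AT2G05540 (-2.04), PMAT2 (AT3G29670, -2.02), AT2G15880 (-1.97) and AT3G44970 (-1.84). SAUR19 (AT5G18010), a small auxin-up RNA gene, was listed at 0 in all white light libraries and stood at 11.9±1.47 TPM at 2 h (adjusted p = 5.19e-05). Of the genes fixed in advance, PIF5 fell (31.4±4.12 against 60.8±6.62 TPM). PIF4 (39±12.7 against 76.6±18.4 TPM, adjusted p = 0.0538) and XTH15 (AT4G14130, 16.2±3.25 against 6.21±2.73 TPM) (adjusted p = 0.13) did not pass. Members of near-identical families (SAUR19 to SAUR24, the LHCB1 genes, small heat shock genes) share reads, so values of single members rest on how the authors' counting split them.

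By list, shade-induced regulators had 8 raised and 1 lowered of 12, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.5e-10). Aux/IAA and GH3 genes had 14 raised and 0 lowered of 31, or 18 and 1 adjusted over the list alone (adjusted p = 3.14e-22), with GH3.5 (AT4G27260, 113±10.4 against 25.4±5.24 TPM, log2 2.12) as a further example. SAUR genes had 5 raised and 0 lowered of 19, or 11 and 1 adjusted over the list alone (adjusted p = 1.96e-09), with SAUR21 (AT5G18030, 57.8±8.17 against 3.95±2.14 TPM, log2 3.66). Cell wall loosening genes had 7 raised and 0 lowered of 21, or 9 and 1 adjusted over the list alone (adjusted p = 2.01e-07). Examples are the xyloglucan endotransglucosylase genes XTH22 (AT5G57560, 163±23.4 against 30.6±5.67 TPM, log2 2.38) and XTH33 (AT1G10550, 11.1±2.67 against 0.837±0.901 TPM, log2 2.82). These 4 lists also pass with an estimated correlation. The next lists pass with the preset correlation alone. Jasmonate synthesis and response had 5 raised and 0 lowered of 14, or 5 and 0 adjusted over the list alone (adjusted p = 1.17e-06, adjusted p = 0.0898 with an estimated correlation). ST2A (AT5G07010, 55.2±7.11 against 3.67±0.951 TPM, log2 3.6) and LOX2 (AT3G45140, 43.7±3.08 against 11.9±3.85 TPM, log2 1.83) rose in it. Ethylene genes had 2 raised and 0 lowered of 15, or 5 and 0 adjusted over the list alone (adjusted p = 0.000737, adjusted p = 0.106 with an estimated correlation), with ACS8 and ACS4 (AT2G22810, 7.51±2.63 against 0.61±0.648 TPM, log2 2.43). Brassinosteroid genes had 3 raised and 0 lowered of 16, or 5 and 0 adjusted over the list alone (adjusted p = 0.00506, adjusted p = 0.332 with an estimated correlation). BEE1 (AT1G18400, 47±4.98 against 5.95±2.09 TPM, log2 2.83) and BRI1 (AT4G39400, 85.4±7.4 against 39.3±0.854 TPM, log2 1.1) rose among them. Gibberellin genes had 3 raised and 0 lowered of 18, or 4 and 0 adjusted over the list alone (adjusted p = 0.00728, adjusted p = 0.106 with an estimated correlation). GA20ox1 (AT4G25420, 8.87±2.45 against 0.757±0.363 TPM, log2 2.48) and GA2ox6 (AT1G02400, 24±2.94 against 2.98±1.36 TPM, log2 2.7) rose among these. Auxin biosynthesis had 3 raised and 0 lowered of 11, or 4 and 0 adjusted over the list alone (adjusted p = 0.0109, adjusted p = 0.264 with an estimated correlation). Growth-regulating HLH factors had 1 raised and 0 lowered of 7, or 3 and 1 adjusted over the list alone (adjusted p = 0.0244, adjusted p = 0.134 with an estimated correlation), with PRE6 (AT1G26945, 219.5±48.8 against 42±9.35 TPM, log2 2.36). Touch and rapid stress genes had 0 raised and 0 lowered of 16, or 3 and 0 adjusted over the list alone (adjusted p = 0.00281, adjusted p = 0.106 with an estimated correlation).

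Other lists lay lower at 2 h. The titles give no hour of harvest, so for clock and antenna genes it cannot be told apart from light. The circadian clock had 0 raised and 5 lowered of 20, or 2 and 9 adjusted over the list alone (adjusted p = 2.31e-05, adjusted p = 0.139 with an estimated correlation). CCA1 (AT2G46830, 27.7±2.15 against 60.3±5.89 TPM, log2 -1.09), LNK1 (AT5G64170, 12.6±0.241 against 29.1±0.534 TPM, log2 -1.14), LNK2 (AT3G54500, 80.6±14.1 against 187±27.3 TPM, log2 -1.21) and RVE1 (AT5G17300, 17±2.42 against 38.9±6.91 TPM, log2 -1.15) fell. The light-harvesting antenna had 0 raised and 2 lowered of 18, or 0 and 12 adjusted over the list alone (adjusted p = 4.12e-10, adjusted p = 0.256 with an estimated correlation). Photomorphogenesis regulators had 0 raised and 0 lowered of 11, or 0 and 1 adjusted over the list alone (adjusted p = 0.0243, adjusted p = 0.274 with an estimated correlation). Phytochromes and PIFs had 3 raised and 3 lowered of 12, or 3 and 4 adjusted over the list alone (adjusted p = 0.332). No list call was made for cytokinin genes (0 raised and 1 lowered of 16, or 2 and 2 adjusted over the list alone, adjusted p = 0.338) or flavonoid synthesis (0 raised and 0 lowered of 12, or 0 and 0 adjusted over the list alone, adjusted p = 0.65). The same holds for heat shock (0 raised and 0 lowered of 6, or 0 and 0 adjusted over the list alone, adjusted p = 0.239). H2A.Z and its remodellers had 0 raised and 0 lowered of 14, or 0 and 0 adjusted over the list alone (adjusted p = 0.735). Root markers had 0 raised and 0 lowered of 16, or 0 and 0 adjusted over the list alone (adjusted p = 0.911). The count of 500 changed genes is 289, 262 and 330 without 2 h replicates 1, 2 and 3. PIF4 passes among genes of mean TPM of at least 1 (adjusted p = 0.0271), with a pseudocount of 0.1 (0.0401), with centring (0.0437) and without 2 h 3 (0.014). The calls end for PIF5 without wild-type white light 1, 2 h 1 or 2 h 2 (adjusted p from 0.0539 to 0.0617), PMAT2 without wild-type white light 1, wild-type white light 3, 2 h 1, 2 h 2 or 2 h 3 (adjusted p from 0.0648 to 0.0816), AT4G34770 without 2 h 1 (adjusted p = 0.0521) and for AT2G15880 without 2 h 1 or 2 h 2 (adjusted p from 0.0676 to 0.0802).

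**Figure D1:**
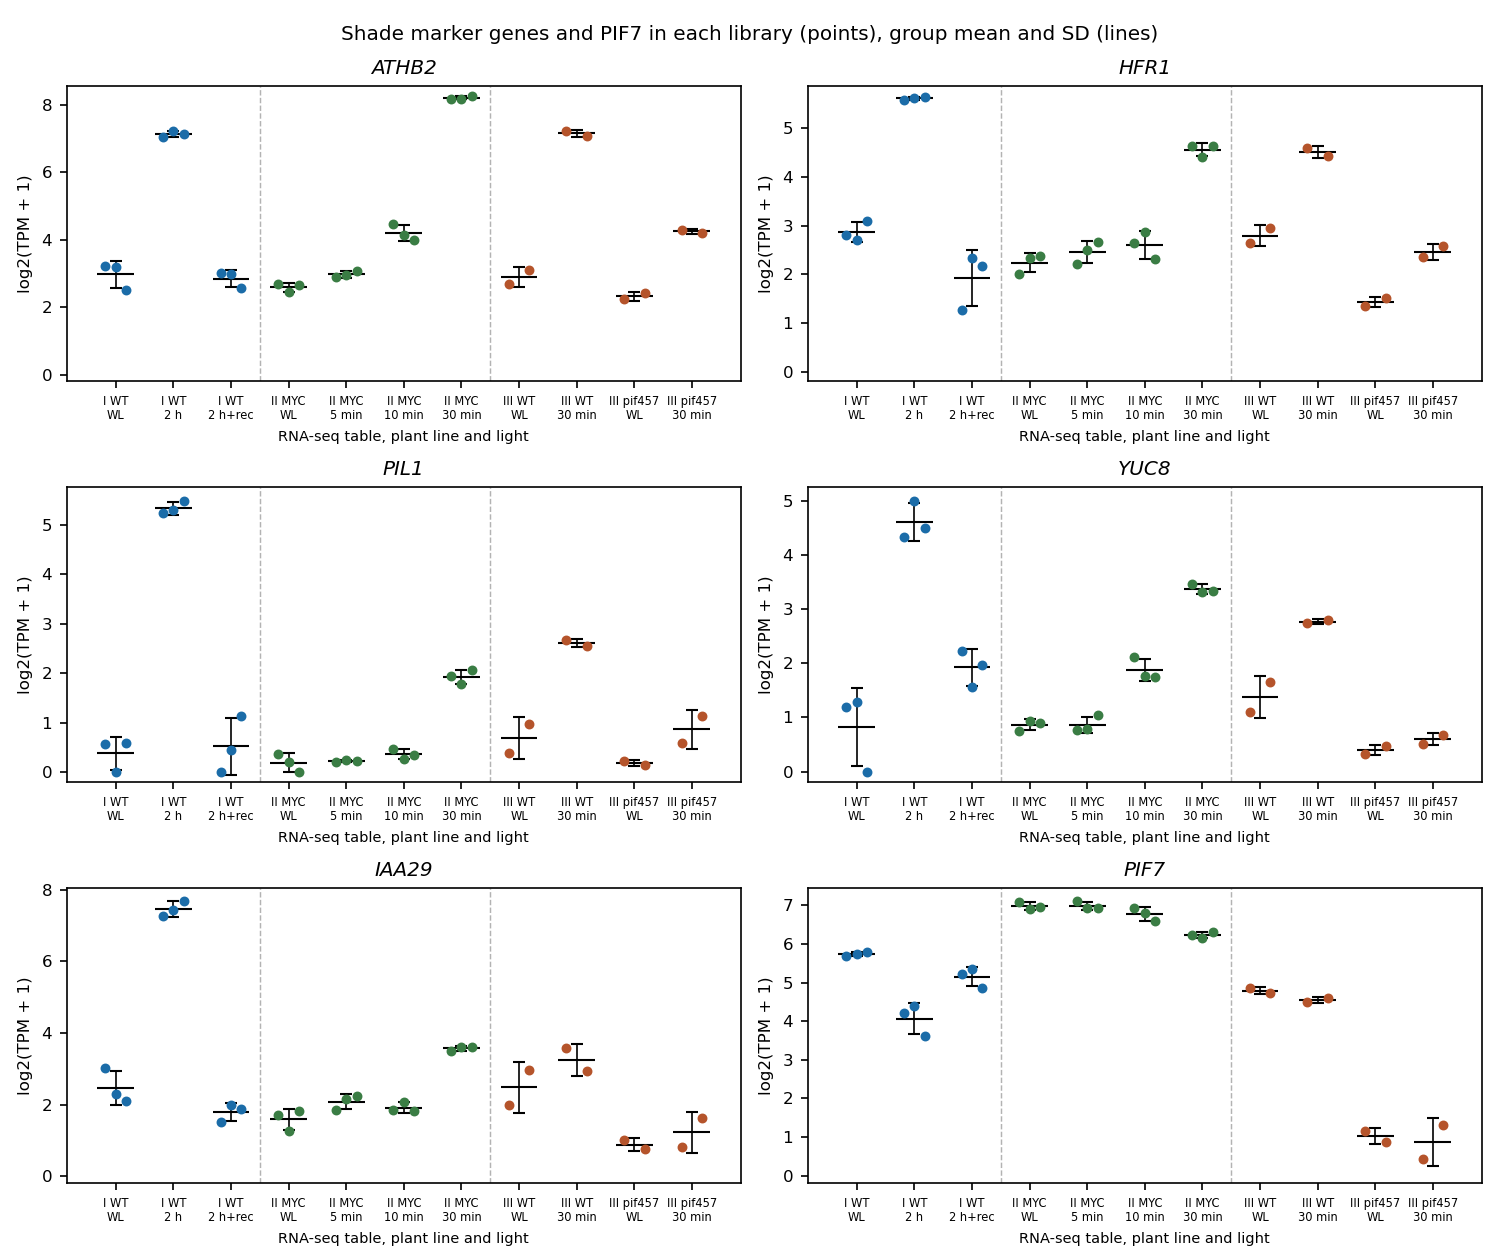
Transcript level of ATHB2, HFR1, PIL1, YUC8, IAA29 and PIF7 in each library of the 3 expression tables. Each point is 1 library, on the scale log2(TPM + 1); the horizontal line is the group mean and the bar its SD (3 libraries per group in tables I and II, 2 in table III). Colours mark the tables, WL is white light, rec is recovery and MYC is the pif457 line carrying PIF7-4xMYC. Tables were made separately, so levels are compared only within a table.

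After 2 h of white light following the 2 h of low R:FR, the shade markers were compared with white light. ATHB2 was at 6.24±1.18 against 7.06±2.03 TPM, PIL1 at 0.523±0.621 against 0.327±0.283 TPM, HFR1 at 2.99±1.41 against 6.33±1.06 TPM and YUC8 at 2.86±0.872 against 0.913±0.794 TPM. IAA29 was at 2.48±0.582 against 4.76±2.02 TPM and IAA19 at 5.31±2.23 against 1.82±0.618 TPM. None of them passed the test (adjusted p from 0.12 to 0.906, 3 libraries each). PIF7 (35±6.1 against 52.6±1.71 TPM), PIF5 (46.9±8.23 against 60.8±6.62 TPM), PIF4 (52.9±2.47 against 76.6±18.4 TPM) and XTH15 (12.8±6.61 against 6.21±2.73 TPM) did not pass either. The cold-regulated genes COR15A (AT2G42540, 59.2±17.2 against 4.63±2.37 TPM, log2 change 3.46, adjusted p = 0.0022) and COR15B (AT2G42530, 94.8±10.3 against 14.9±5.25 TPM, log2 2.63) and the florigen gene FT (AT1G65480, 6.86±0.95 against 0.31±0.537 TPM, log2 2.65) rose. So did UPM1 (AT5G40850, 286±24.5 against 55.6±5.34 TPM, log2 2.34) and G6PD3 (AT1G24280, 31±2.42 against 6.34±1.85 TPM, log2 2.15), which encode a siroheme synthesis enzyme and a plastid glucose-6-phosphate dehydrogenase. AT5G14920 (1151±104 against 232±27.7 TPM, log2 2.31) rose too, and AT1G66100 (36.2±11.6 against 132±6.44 TPM, log2 -1.88) and MAKR6 (AT5G52900, 6.04±1.03 against 20.7±3.44 TPM, log2 -1.62) fell.

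Against white light 100 genes were raised and 80 lowered after recovery. The split is 196 and 132 after rRNA and organellar transcripts are removed, 152 and 160 with each library centred on its median gene and 188 and 173 among genes of mean TPM of at least 1. Of the 100 and 80 genes, 42 were raised and 44 lowered at 2 h too (1.24 and 0.59 expected of independent lists), and both comparisons use the same white light libraries, so part of the excess may come from them. Jasmonate genes had 3 raised and 0 lowered of 14, or 4 and 0 adjusted over the list alone (adjusted p = 3.34e-05, adjusted p = 0.108 with an estimated correlation). LOX2 (49.7±0.484 against 11.9±3.85 TPM), AOC2 (AT3G25770, 241±5.77 against 115±17.3 TPM, log2 1.07) and AOS (AT5G42650, 134±14.9 against 69.6±5.38 TPM, log2 0.93) rose. Cell wall loosening genes had 3 raised and 0 lowered of 21, or 6 and 1 adjusted over the list alone (adjusted p = 0.000261, adjusted p = 0.106 with an estimated correlation). The light-harvesting antenna had 0 raised and 3 lowered of 18, or 0 and 14 adjusted over the list alone (adjusted p = 4.19e-14, adjusted p = 0.165 with an estimated correlation), with LHCB2.3 (AT3G27690, 697±108 against 1598±349 TPM, log2 -1.19). The clock had 0 raised and 3 lowered of 20, or 2 and 8 adjusted over the list alone (adjusted p = 0.00281, adjusted p = 0.274 with an estimated correlation), with CCA1 at 26.3±1.04 against 60.3±5.89 TPM and LNK2 at 81.9±16 against 187±27.3 TPM. SAUR genes lay lower as a list, 0 raised and 0 lowered of 19, or 0 and 4 adjusted over the list alone, with SAUR66 (AT1G29500, 6.46±0.863 against 19.7±5.38 TPM). Their adjusted p = 2.07e-05, and adjusted p = 0.0425 with an estimated correlation. Some lists lay lower with no single member past the test across all genes. They are Aux/IAA and GH3 genes (0 raised and 0 lowered of 31, or 2 and 7 adjusted over the list alone, adjusted p = 0.0225, adjusted p = 0.352 with an estimated correlation). Growth-regulating HLH factors had 0 raised and 0 lowered of 7, or 0 and 1 adjusted over the list alone (adjusted p = 0.0141, adjusted p = 0.107 with an estimated correlation). Heat shock genes had 0 raised and 0 lowered of 6, or 0 and 0 adjusted over the list alone (adjusted p = 0.0145, adjusted p = 0.363 with an estimated correlation). The count of 180 is 61, 63 and 51 without recovery replicates 1, 2 and 3. With only these groups fitted the call on LHCB2.3 ends, and SAUR66 passes among genes of mean TPM of at least 1 (adjusted p = 0.0256), with a pseudocount of 0.1 (0.0346) and with either scaling (0.0437 and 0.039). The calls end for LNK2 without wild-type white light 1, wild-type white light 3, recovery 2 or recovery 3 (adjusted p from 0.0527 to 0.0844) and for LHCB2.3 without wild-type white light 2, recovery 1, recovery 2 or recovery 3 (adjusted p from 0.052 to 0.0835), and those on the other genes named here hold in every alternative tried.

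Against the 2 h libraries the recovery libraries held less of the shade transcripts. ATHB2 fell by 4.3 on the log2 scale (6.24±1.18 against 140.2±8.44 TPM, adjusted p = 8.39e-06), IAA29 by 5.68 (2.48±0.582 against 177±27 TPM). PIL1 fell by 4.8, HFR1 by 3.69, GH3.3 by 4.37, IAA19 by 3.78 and YUC8 by 2.69 (3 libraries each). MAKR6 fell from 177±9.63 to 6.04±1.03 TPM. PRE6 fell from 219.5±48.8 to 19.3±4.49. The nitrate reductase gene NIA1 (AT1G77760, 447±55 against 80.1±13.5 TPM, log2 change 2.47, adjusted p = 0.0048) and the GATA factor gene CGA1 (AT4G26150, 30.9±4.86 against 10.1±1.6 TPM, log2 1.52) rose. The asparagine synthetase gene ASN2 (AT5G65010, 243±27.3 against 87.2±20.2 TPM, log2 1.49) and MES10 (AT3G50440, 27.7±6.25 against 3.4±1.29 TPM, log2 2.73) rose. PIF1 (52±1.8 against 28.1±2.42 TPM) and PIF7 (35±6.1 against 16.2±4.48 TPM) rose as well. PIF4 (log2 change 0.47), PIF5 (0.56) and XTH15 (-0.42) did not pass.

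In this comparison 91 genes rose and 189 fell. Among the fallen lists, SAUR genes had 0 raised and 9 lowered of 19, or 0 and 15 adjusted over the list alone (adjusted p = 1.1e-26). Aux/IAA and GH3 genes had 0 raised and 15 lowered of 31, or 1 and 19 adjusted over the list alone (adjusted p = 8.87e-36). Shade-induced regulators had 0 raised and 5 lowered of 12, or 0 and 9 adjusted over the list alone (adjusted p = 2.17e-18). Growth-regulating HLH factors had 0 raised and 1 lowered of 7, or 0 and 3 adjusted over the list alone (adjusted p = 1.79e-06). Gibberellin genes had 0 raised and 3 lowered of 18, or 0 and 5 adjusted over the list alone (adjusted p = 7.05e-05). Touch genes had 0 raised and 0 lowered of 16, or 0 and 6 adjusted over the list alone (adjusted p = 2.92e-07). 3 more lists are lost with an estimated correlation. Auxin biosynthesis had 0 raised and 2 lowered of 11, or 0 and 3 adjusted over the list alone (adjusted p = 0.0202, adjusted p = 0.297 with an estimated correlation). Brassinosteroid genes had 0 raised and 4 lowered of 16, or 3 and 5 adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.352 with an estimated correlation). Ethylene genes had 1 raised and 3 lowered of 15, or 1 and 5 adjusted over the list alone (adjusted p = 0.0118, adjusted p = 0.194 with an estimated correlation). Raised at 2 h and lowered again were 129 genes. Independent lists would share 2.34. In 20 simulations with all libraries drawn anew and no gene changed, 0 were shared on average. With no gene changed few calls can arise, so the simulations do not measure what common 2 h libraries add. Both comparisons use these 2 h libraries, and groups of 3 cannot be split into separate controls, so part of the excess may come from them. The count of 280 is 173 and 175 without 2 h replicates 1 and 3, and 180, 157 and 179 without recovery replicates 1, 2 and 3. With a pseudocount of 0.1 the call on YUC8 ends and with only these groups fitted that on PIF7. The calls end for PIF7 without 2 h 1, 2 h 3, recovery 1 or recovery 2 (adjusted p from 0.0635 to 0.152) and for YUC8 without recovery 2 (adjusted p = 0.0513).

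After 5 min of low R:FR transcripts of the PIF7-MYC line differed from those in white light. The flavonoid genes CHS (AT5G13930, 49.2±13 against 139±13.6 TPM, log2 change -1.51, adjusted p = 0.00347), CHI (AT3G55120, 21.3±1.65 against 37.7±2.45 TPM, log2 -0.80) and FLS1 (AT5G08640, 13.4±2.21 against 31.1±1.89 TPM, log2 -1.17), which encode chalcone synthase, chalcone isomerase and flavonol synthase, fell. CYP83A1 (AT4G13770, 0.56±0.288 against 8.05±2.87 TPM, log2 -2.5), a glucosinolate synthesis gene, and NAS1 (AT5G04950, 10.2±2.81 against 27.2±4.91 TPM, log2 -1.34), a nicotianamine synthase gene, fell too. The leucine breakdown gene MCCA (AT1G03090, 56.3±6.33 against 19.6±2.04 TPM, log2 1.47), AT4G36850 (138±16.1 against 44.8±5.35 TPM, log2 1.6) and AT5G07842 (14.9±2.81 against 4.09±0.358 TPM, log2 1.63) rose. So did PHYA (AT1G09570, 42.2±5.15 against 28.5±1.66 TPM, log2 0.55), a phytochrome gene and XTH24 (AT4G30270, 243±16.6 against 125±14.8 TPM, log2 0.95) (3 libraries each). ATHB2 (6.83±0.515 against 5.04±0.549 TPM, adjusted p = 0.0975), PIL1 (log2 change 0.04), and HFR1 (0.22) did not pass. Nor did YUC8 (0.827±0.194 against 0.827±0.121 TPM), IAA19 (-0.63), IAA29 (0.49), XTH15 (-0.30), PIF4 (0.46), PIF5 (0.18) and PIF7 (126±9.25 against 126±8.71 TPM).

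At 5 min 634 genes were raised and 321 lowered of 24589 tested, of which 39 and 36 by at least 2-fold. With each library centred on its median gene the split is 605 and 611. Flavonoid and anthocyanin genes had 0 raised and 5 lowered of 12, or 0 and 8 adjusted over the list alone (adjusted p = 2.7e-10, adjusted p = 0.0762 with an estimated correlation). Clock genes had 5 raised and 0 lowered of 20, or 10 and 0 adjusted over the list alone (adjusted p = 3.34e-05, adjusted p = 0.383 with an estimated correlation), with RVE4 (AT5G02840, 148±12.1 against 96.3±3.14 TPM, log2 0.61) and LUX (AT3G46640, 36.2±4.14 against 23.4±4.16 TPM, log2 0.62). Phytochromes and PIFs lay higher (1 raised and 0 lowered of 12, or 2 and 0 adjusted over the list alone, adjusted p = 0.0279, adjusted p = 0.547 with an estimated correlation). So did brassinosteroid genes (1 raised and 0 lowered of 16, or 5 and 1 adjusted over the list alone, adjusted p = 0.0461, adjusted p = 0.333 with an estimated correlation). Shade-induced regulators had 1 raised and 0 lowered of 12, or 2 and 0 adjusted over the list alone (adjusted p = 0.11). The count of 955 is 464 and 414 without white light replicates 1 and 3, and 382, 474 and 218 without 5 min replicates 1, 2 and 3. PIF4 passes among genes of mean TPM of at least 1 (adjusted p = 0.0296) and with a pseudocount of 0.1 (0.0442). The call on LUX ends with a replicate block and with only these groups fitted. The calls end for RVE4 without white light 3, 5 min 1 or 5 min 3 (adjusted p from 0.0532 to 0.071) and for LUX without 5 min 2 or 5 min 3 (adjusted p from 0.0612 to 0.0962), and those on the other genes named here hold in every alternative tried.

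After 10 min ATHB2, which had not passed at 5 min, rose to 17.5±3.17 against 5.04±0.549 TPM (log2 change 1.6, adjusted p = 0.000583). Its relative HAT1 (AT4G17460, 44.2±4.63 against 27.1±2.41 TPM, log2 0.69) rose with it. So did YUC8 (2.7±0.561 against 0.827±0.121 TPM, log2 change 1.01) and the cytokinin oxidase gene CKX5 (AT1G75450, 0.85±0.106 against 0.25±0.030 TPM, log2 0.56) (3 libraries each). The copper protein gene BCB (AT5G20230, 7.06±3.55 against 67±18.1 TPM, log2 -3.14) and the early light-inducible gene ELIP2 (AT4G14690, 24.3±4.75 against 131±19.5 TPM, log2 -2.39) fell. The plastid fibrillin gene FIB (AT4G04020, 242±17.2 against 880.2±189 TPM, log2 -1.84) and CHI (25±1.88 against 37.7±2.45 TPM) fell. XTH15 rose (10.1±0.692 against 5.49±1.55 TPM). PIL1 (log2 change 0.17), HFR1 (0.36), IAA19 (0.04), IAA29 (0.33), PIF4 (0.06), PIF5 (-0.13) and PIF7 (-0.21) did not pass.

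At 10 min 1030 genes were raised and 552 lowered, 91 and 46 by at least 2-fold. The split is 907 and 999 with each library centred on its median gene. Cytokinin genes had 8 raised and 0 lowered of 16, or 9 and 0 adjusted over the list alone (adjusted p = 0.000152, adjusted p = 0.158 with an estimated correlation). The response regulator genes ARR5 (AT3G48100, 10.8±0.966 against 4.14±1.24 TPM, log2 1.22) and ARR6 (AT5G62920, 12.8±1.23 against 4.3±1.97 TPM, log2 1.45) rose. Shade-induced regulators had 4 raised and 0 lowered of 12, or 4 and 0 adjusted over the list alone (adjusted p = 0.012, adjusted p = 0.199 with an estimated correlation), with ATHB4 (AT2G44910, 6.31±1.44 against 2.94±0.613 TPM, log2 0.88) and PAR1 (AT2G42870, 7.87±1.59 against 3.72±0.316 TPM, log2 0.90). Auxin biosynthesis had 4 raised and 0 lowered of 11, or 6 and 0 adjusted over the list alone (adjusted p = 0.0163, adjusted p = 0.199 with an estimated correlation), with YUC5 (AT5G43890, 1.96±0.681 against 0.523±0.155 TPM, log2 0.94). Gibberellin genes (1 raised and 0 lowered of 18, or 5 and 0 adjusted over the list alone, adjusted p = 0.0429, adjusted p = 0.347 with an estimated correlation) lay higher. Heat shock genes lay lower (0 raised and 1 lowered of 6, or 0 and 3 adjusted over the list alone, adjusted p = 0.000265, adjusted p = 0.347 with an estimated correlation). So did touch genes (0 raised and 1 lowered of 16, or 0 and 1 adjusted over the list alone, adjusted p = 0.00443, adjusted p = 0.547 with an estimated correlation). Photomorphogenesis regulators did too (0 raised and 1 lowered of 11, or 0 and 1 adjusted over the list alone, adjusted p = 0.0326, adjusted p = 0.547 with an estimated correlation). Root markers moved with this time point: 2 raised and 0 lowered of 16, or 11 and 0 adjusted over the list alone (adjusted p = 0.00213, adjusted p = 0.547 with an estimated correlation). Their mean log2 level was 2.07, 2.14 and 2.23 in the 10 min libraries against 0.965, 1.86 and 1.26 in white light. The count of 1582 is 257, 3542 and 106 without white light replicates 1, 2 and 3. It is 375, 796 and 187 without 10 min replicates 1, 2 and 3. With only these groups fitted the calls on XTH15, ARR5, ARR6, ATHB4, PAR1 and YUC5 end. They also end for XTH15 without white light 1, white light 3 or 10 min 3 (adjusted p from 0.0565 to 0.0831), ARR6 without 10 min 3 (adjusted p = 0.0523), ATHB4 and YUC5 without white light 3 or 10 min 3 (adjusted p from 0.0506 to 0.0739) and for PAR1 without white light 3 (adjusted p = 0.0575). Calls on the other genes named here hold in every alternative in which the gene was tested.

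**Figure D2:**
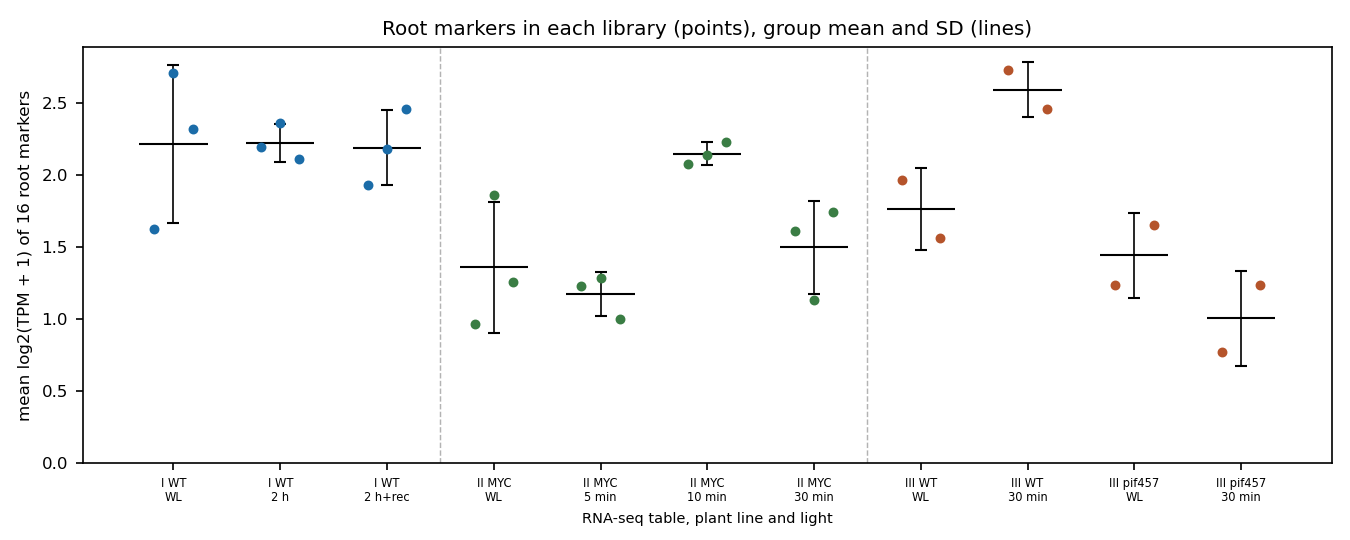
Mean level of 16 root marker genes in each library. Each point is 1 library, given as the mean of log2(TPM + 1) over the markers; the horizontal line is the group mean and the bar its SD (3 libraries per group in tables I and II, 2 in table III). Colours mark the tables, WL is white light, rec is recovery and MYC is the pif457 line carrying PIF7-4xMYC.

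At 30 min the shade response of the PIF7-MYC line was strong. ATHB2 stood at 293±8.83 against 5.04±0.549 TPM (log2 change 5.61, adjusted p = 2.98e-09, 3 libraries each). ATHB4 (92.8±3.04 against 2.94±0.613 TPM), HAT1 (226±14.7 against 27.1±2.41 TPM), PAR1 (28.7±3.16 against 3.72±0.316 TPM), HFR1 (22.6±2.22 against 3.75±0.63 TPM) and PIL1 (2.82±0.385 against 0.15±0.15 TPM) rose. The auxin synthesis genes YUC8 (9.39±0.622 against 0.827±0.121 TPM), YUC9 (4.99±0.335 against 0.223±0.123 TPM) and YUC5 (4.53±0.294 against 0.523±0.155 TPM) rose. So did the brassinosteroid synthesis genes DWF4 (AT3G50660, 41.1±2.66 against 10.6±0.872 TPM, log2 1.85) and BR6OX2 (AT3G30180, 44.1±8.1 against 9.26±2.38 TPM, log2 2.15). The brassinosteroid-related bHLH gene BIM1 (AT5G08130, 215±20.1 against 34±2.5 TPM, log2 2.62) and the cold-response factor gene CBF1 (AT4G25490, 2.46±0.47 against 0.0933±0.0814 TPM, log2 1.65) rose too. IAA29 rose to 10.9±0.609 against 2.04±0.59 TPM. IAA19 (3.77±0.34 against 3.47±0.838 TPM), XTH15 (7.14±0.439 against 5.49±1.55 TPM), PIF4 (16.1±1.51 against 14.4±1.23 TPM) and PIF5 (3.14±0.0781 against 4.2±1.09 TPM) did not pass. PIF7 fell (74.3±4.32 against 126±8.71 TPM, log2 change -0.76). So did the MYB factor gene MYB16 (AT5G15310, 13.2±0.883 against 28.8±3.86 TPM, log2 -1.07), FLS1 (15.9±1.75 against 31.1±1.89 TPM) and CYP83A1 (0.887±0.844 against 8.05±2.87 TPM).

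In all 934 genes were raised and 254 lowered at 30 min, 149 and 20 by at least 2-fold. The split is 647 and 514 with each library centred on its median gene. Further large rises were in AT5G66080 (2.43), AT5G54530 (2.42), AT3G07350 (2.42) and WRKY22 (AT4G01250, 2.36), and falls in AT5G62210 (-1.66) and AT3G44450 (-1.14). Shade-induced regulators had 10 raised and 0 lowered of 12, or 10 and 2 adjusted over the list alone (adjusted p = 1.03e-16). Brassinosteroid genes had 10 raised and 0 lowered of 16, or 13 and 0 adjusted over the list alone (adjusted p = 1.2e-12). Both pass with an estimated correlation. Auxin biosynthesis lay higher (4 raised and 0 lowered of 11, or 5 and 1 adjusted over the list alone, adjusted p = 0.00243, adjusted p = 0.158 with an estimated correlation). Aux/IAA and GH3 genes had 5 raised and 0 lowered of 31, or 7 and 0 adjusted over the list alone (adjusted p = 0.0288, adjusted p = 0.239 with an estimated correlation), with IAA16 (AT3G04730, 247±19.7 against 112±8.0 TPM, log2 1.14). Gibberellin genes had 5 raised and 0 lowered of 18, or 7 and 1 adjusted over the list alone (adjusted p = 0.00143, adjusted p = 0.158 with an estimated correlation), with GAI (AT1G14920, 44.2±4.96 against 21.5±3.21 TPM, log2 1.01). Growth-regulating HLH factors had 2 raised and 0 lowered of 8, or 3 and 0 adjusted over the list alone (adjusted p = 0.0326, adjusted p = 0.199 with an estimated correlation), with PRE1 (AT5G39860, 15±0.574 against 4.32±1.53 TPM, log2 1.63). Flavonoid genes had 0 raised and 4 lowered of 12, or 0 and 7 adjusted over the list alone (adjusted p = 3.15e-09, adjusted p = 0.0806 with an estimated correlation). The light-harvesting antenna lay lower with no single call (adjusted p = 0.00256, adjusted p = 0.705 with an estimated correlation). SAUR genes gave no list call (1 raised and 0 lowered of 19, or 4 and 1 adjusted over the list alone, adjusted p = 0.49). Nor did the clock (3 raised and 1 lowered of 20, or 7 and 1 adjusted over the list alone, adjusted p = 0.409) or root markers (0 raised and 0 lowered of 16, or 0 and 0 adjusted over the list alone, adjusted p = 0.717). The count of 1188 is 667 and 561 without white light replicates 1 and 3, and 541 and 497 without 30 min replicates 1 and 3. The calls on the genes named here hold in every alternative in which the gene was tested, as filters on low TPM can drop a gene. XTH15 passes without white light 2 (adjusted p = 0.0191).

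The 3 times share white light libraries, and the lists overlap. 305 genes were raised at both 5 and 30 min (24.1 expected of independent lists). Shared are 164 at both 10 and 30 min (39.1 expected) and 101 at both 5 and 10 min (26.6 expected). Lowered genes shared number 99, 67 and 54, against 3.32, 5.7 and 7.21. Of the genes raised at 5 min 48.1% were raised at 30 min and 15.9% at 10 min, which does not follow the order of times. The cause was not tested. In 20 simulations with all libraries drawn anew and no gene changed, at most 1 gene was shared. Few calls can then arise, so this does not measure what the common white light libraries add. As these 3 libraries cannot be split, part of the excess may come from them.

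**Figure D3:**
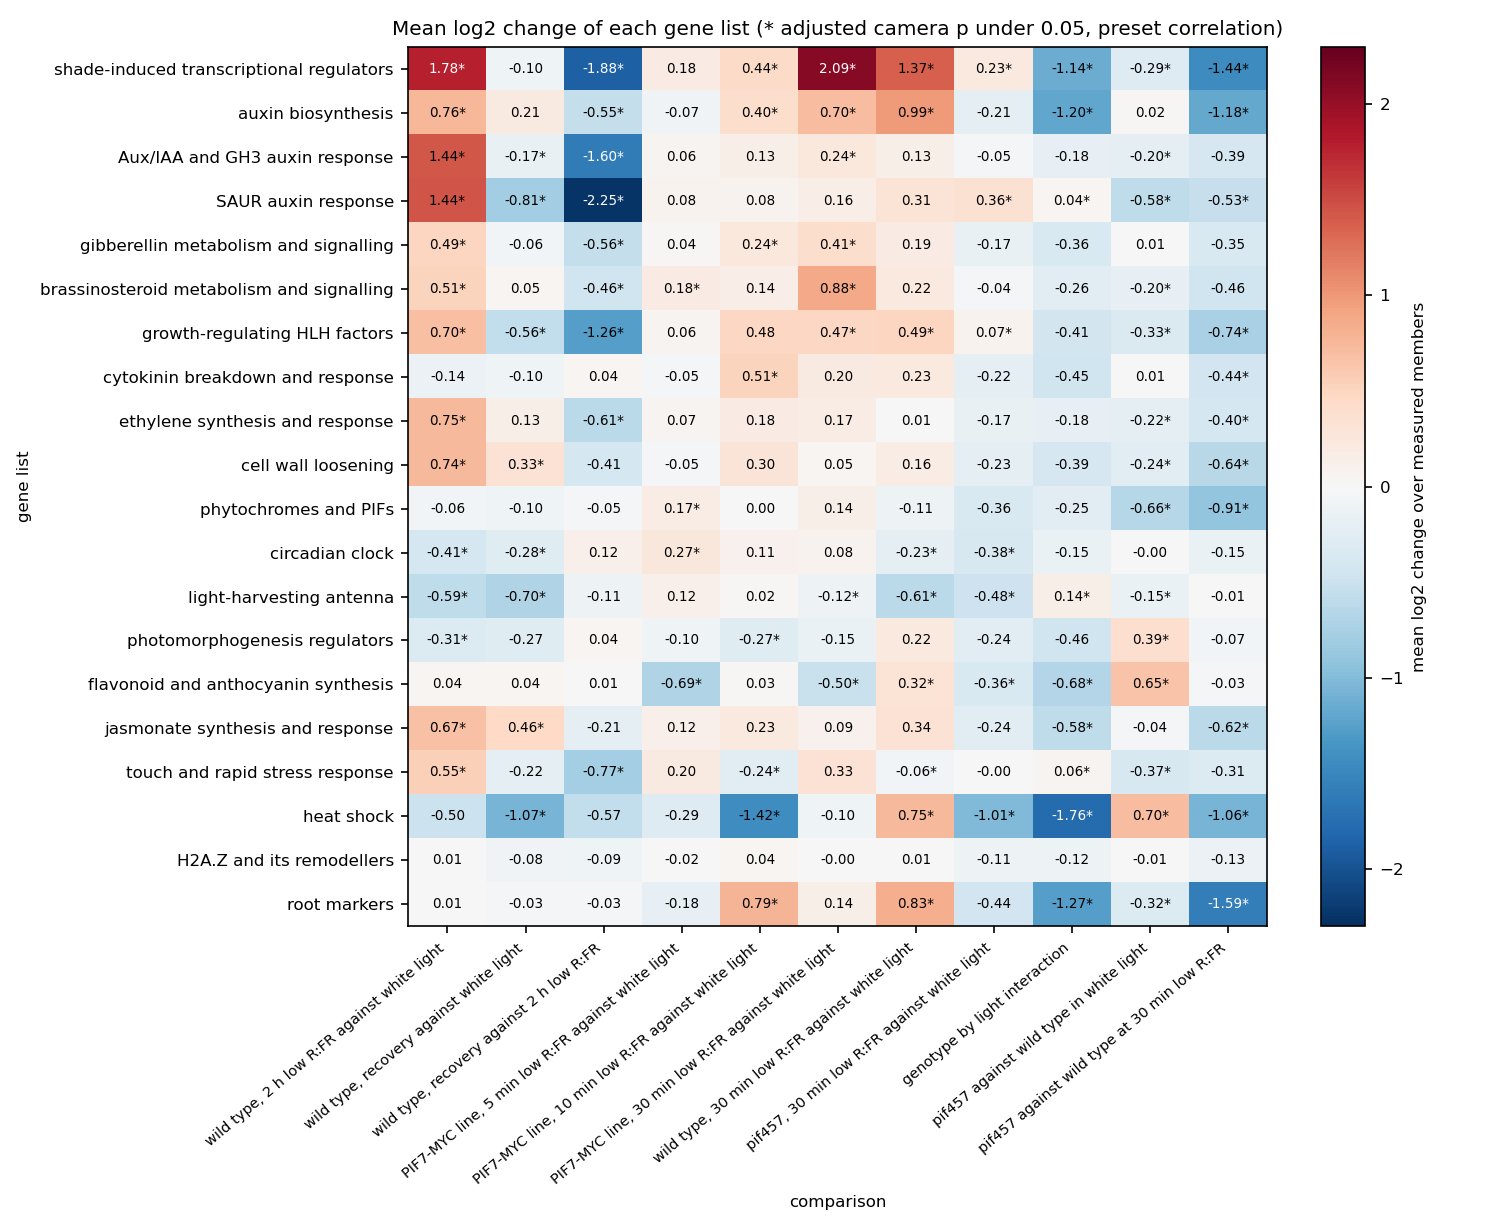
Mean log2 change of each of the 20 gene lists in the 11 comparisons. Each cell is the mean over the measured members of the list, red for higher and blue for lower in the group named first, and an asterisk marks a list past the camera test with the preset correlation. Most of these calls are lost when the correlation is estimated from the libraries.

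In wild type of table III, 30 min of low R:FR raised the same marker and its relatives. ATHB2 stood at 141±11.1 against 6.53±1.58 TPM (log2 change 4.25, adjusted p = 0.000469). ATHB4 stood at 82.1±7.01 against 3.56±0.106 TPM (log2 change 4.19), YUC9 at 16.8±1.34 against 0.36±0.198 TPM (log2 change 3.72) and YUC5 at 8.38±0.912 against 0.495±0.00707 TPM (2 libraries each). HAT1 (86.9±1.49 against 24.2±3.09 TPM), HFR1 (21.8±1.88 against 5.97±1.05 TPM) and PIL1 (5.12±0.318 against 0.645±0.474 TPM) rose as well. YUC8 (5.83±0.219 against 1.64±0.70 TPM, adjusted p = 0.0625), and IAA29 (log2 change 0.78) did not pass. Nor did IAA19 (0.24), XTH15 (0.35), PIF4 (14.3±0.771 against 39.8±10.3 TPM, adjusted p = 0.146), PIF5 (-0.86) and PIF7 (-0.24).

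With limma 29 genes were raised and 0 lowered of 24384 tested, with 2128 at an unadjusted p under 0.05. The split is 258 and 121 with each library centred on its median gene and 486 and 133 among genes of mean TPM of at least 1. Shade-induced regulators had 6 raised and 0 lowered of 12, or 8 and 1 adjusted over the list alone (adjusted p = 3.29e-11, adjusted p = 0.466 with an estimated correlation). Auxin biosynthesis had 2 raised and 0 lowered of 11, or 5 and 0 adjusted over the list alone (adjusted p = 3.48e-08, adjusted p = 0.466 with an estimated correlation). The light-harvesting antenna lay lower, 0 raised and 0 lowered of 18, or 0 and 12 adjusted over the list alone, with LHCB1.2 (AT1G29910, 2192±159.8 against 4463±719.8 TPM) (adjusted p = 2.4e-20, adjusted p = 0.466 with an estimated correlation). The clock lay lower too (0 raised and 0 lowered of 20, or 0 and 0 adjusted over the list alone, adjusted p = 0.000155, adjusted p = 0.701 with an estimated correlation). Touch genes had 0 raised and 0 lowered of 16, or 0 and 2 adjusted over the list alone and lay lower (adjusted p = 0.0478, adjusted p = 0.651 with an estimated correlation). Growth-regulating HLH factors lay higher (0 raised and 0 lowered of 8, or 2 and 0 adjusted over the list alone, adjusted p = 0.0262, adjusted p = 0.58 with an estimated correlation), with PRE1 (13±1.46 against 3.92±1.14 TPM). Flavonoid genes had 0 raised and 0 lowered of 12, or 0 and 0 adjusted over the list alone and lay higher (adjusted p = 0.00901, adjusted p = 0.701 with an estimated correlation). Heat shock genes did too (0 raised and 0 lowered of 6, or 2 and 0 adjusted over the list alone, adjusted p = 0.00868, adjusted p = 0.58 with an estimated correlation). Root markers moved with this light condition: 0 raised and 0 lowered of 16, or 10 and 1 adjusted over the list alone (adjusted p = 7.89e-07, adjusted p = 0.58 with an estimated correlation). Their mean log2 level was 2.73 and 2.46 after 30 min against 1.97 and 1.56 in white light. H2A.Z and its remodellers gave no call (adjusted p = 0.664), and their mean log2 change of 0.01 has the sign opposite to the test. The calls on ATHB2, ATHB4 and YUC9 hold in every alternative tried, and those on YUC5, HAT1, HFR1 and PIL1 end with only these 2 groups fitted. They also end for HFR1 and PIL1 with a pseudocount of 0.1, for HFR1 with a replicate block and for HAT1, HFR1 and PIL1 without any 1 of the 4 libraries (adjusted p from 0.0705 to 0.324). The count of 29 is 19 without white light replicate 2. Calls are gained among genes of mean TPM of at least 1 for LHCB1.2 (adjusted p = 6.71e-07), PIF4 (2.19e-06), PRE1 (3.1e-06), YUC8 (6.47e-05) and PIF5 (0.0258), and all 5 pass with centring too (0.0144 to 0.0479).

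In pif457 no fixed gene passed the test after the same 30 min when all genes were tested, and some do in alternatives given below. ATHB2 stood at 17.9±0.799 against 4.01±0.453 TPM (log2 change 1.92, adjusted p = 0.0562), HFR1 at 4.53±0.629 against 1.7±0.205 TPM and PIL1 at 0.86±0.495 against 0.14±0.0424 TPM. YUC8 stood at 0.515±0.12 against 0.32±0.0848 TPM, IAA29 at 1.44±0.948 against 0.85±0.24 TPM, IAA19 at 1.8±0.502 against 2.0±0.566 TPM and XTH15 at 3.38±0.856 against 3.92±1.68 TPM (2 libraries each). YUC5 stood at 0.17±0.0424 against 0.67±0.297 TPM, PIF4 at 4.74±2.29 against 11.6±0.431 TPM, PIF5 at 2.02±0.601 against 3.37±0.933 TPM and PIF7 at 0.91±0.792 against 1.04±0.283 TPM. AT1G18382 and AT3G41761 were called raised and MIR848 (AT5G13887) lowered (named after their values were seen, the first 2 listed at 0 in white light and MIR848 at 0 after 30 min), with 2293 genes at an unadjusted p under 0.05. The split is 9 and 11 after rRNA and organellar transcripts are removed, 74 and 93 with each library centred on its median gene and 82 and 511 among genes of mean TPM of at least 1.

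Lists in pif457 at 30 min had no member past the test across all genes. SAUR genes lay higher (3 members raised over the list alone, such as SAUR20 (AT5G18020, 13.9±2.12 against 4.82±0.0919 TPM), adjusted p = 2.22e-09). The antenna lay lower (5 members lowered over the list alone, such as LHCB1.2 at 1419±211 against 3161±288 TPM, adjusted p = 1.36e-05). So did the clock (adjusted p = 0.047), flavonoid genes (adjusted p = 0.026) and heat shock genes (adjusted p = 0.00868). The test placed shade-induced regulators higher (adjusted p = 0.000274), their mean being 0.23 and their median -0.09, and growth-regulating HLH factors higher (adjusted p = 0.00868). All of these are lost (adjusted p from 0.466 to 0.872 with an estimated correlation). For Aux/IAA, gibberellin, brassinosteroid, photomorphogenesis, touch and H2A.Z lists the mean change was negative and the test pointed up, none past the threshold. The median of all genes above 5 TPM shifted by -0.174. Library pif457 30 min replicate 1 held 23.1% of its TPM in rRNA and organellar transcripts, the highest of the 29 libraries. The count of 3 is 22 and 25 without pif457 white light replicates 1 and 2. It is 15 and 5511 without 30 min replicates 1 and 2. ATHB2 passes among genes of mean TPM of at least 1 (adjusted p = 1.08e-12), with a pseudocount of 0.1 (0.0132), with only these 2 groups fitted (0.0146) and with either scaling (0.0478 and 0.00614). The filter leaves its log2 change at 1.92, so its lower p comes from the variance shared among genes and from the genes tested. HFR1, PIF4, LHCB1.2 and SAUR20 pass with that filter (0.00632, 0.000136, 8.46e-09 and 1.52e-05). Without 30 min replicate 2 the group is replicate 1 alone, the library with 23.1% of TPM in rRNA and organellar transcripts. The log2 changes are then 1.96 for ATHB2, 0.917 for HFR1, -1.609 for PIF4, -1.312 for LHCB1.2 and 1.202 for SAUR20. HFR1 (0.019) and SAUR20 (0.00182) also pass with centring, SAUR20 with rRNA and organellar transcripts removed (0.0238) and LHCB1.2 with only these 2 groups fitted (0.00119).

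The light response differed between pif457 and wild type at 10 genes by the interaction term (8 lower and 2 higher in pif457, 2818 at an unadjusted p under 0.05). The split is 144 lower and 48 higher with each library centred on its median gene and 732 lower and 74 higher among genes of mean TPM of at least 1. ATHB4 changed by 4.19 in wild type and by -0.10 in pif457 on the log2 scale, YUC9 by 3.72 and -0.22, and YUC5 by 2.65 and -0.50. The interactions are -4.29, -3.93 and -3.15 (adjusted p = 0.00883 for each). The iron superoxide dismutase gene FSD1 (AT4G25100) went the other way, with an interaction of 2.65. ATHB2 had -2.33 (adjusted p = 0.0528) and did not pass. Nor did HFR1 -0.68, PIL1 -1.24, YUC8 -1.2, IAA29 -0.43, IAA19 -0.34, XTH15 -0.49, PIF4 0.20, PIF5 0.34 and PIF7 0.09. Auxin biosynthesis (0 raised and 2 lowered of 11, or 0 and 5 adjusted over the list alone, adjusted p = 2.16e-06) and shade-induced regulators (0 raised and 1 lowered of 12, or 0 and 6 adjusted over the list alone, adjusted p = 1.03e-05) lay lower. So did heat shock genes (adjusted p = 0.000713), flavonoid genes (adjusted p = 0.0017), jasmonate genes (adjusted p = 0.0447) and root markers (0 raised and 0 lowered of 16, or 0 and 10 adjusted over the list alone, adjusted p = 8.86e-06). These are lost (adjusted p from 0.466 to 0.701 with an estimated correlation).

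The antenna lay higher in the interaction (adjusted p = 7.28e-05, adjusted p = 0.596 with an estimated correlation). By the test SAUR genes lay higher (adjusted p = 0.00868, adjusted p = 0.651 with an estimated correlation). Touch genes did so too (adjusted p = 0.00855, adjusted p = 0.58 with an estimated correlation), the touch median being -0.07 and its mean 0.06. The median of all genes above 5 TPM shifted by -0.228. The count of 10 is 21 and 16 without pif457 white light replicates 1 and 2, 29 without wild-type 30 min replicate 2 and 3145 without pif457 30 min replicate 2. ATHB2 passes among genes of mean TPM of at least 1 (adjusted p = 1.54e-09) and with centring (0.019). PIL1 passes with that filter (0.0436) and YUC8 with 1 TPM in 2 libraries (0.0445). Without pif457 30 min replicate 2, which leaves replicate 1 alone in its group, the interactions are -2.29 for ATHB2 and -1.52 for PIL1. The call on YUC9 ends with a pseudocount of 0.1, and the calls end for ATHB4 without wild-type white light 1, wild-type white light 2, pif457 white light 2, wild-type 30 min 1 or wild-type 30 min 2 (adjusted p from 0.0528 to 0.1), YUC5 without wild-type white light 1, wild-type white light 2 or pif457 30 min 1 (adjusted p from 0.0514 to 0.086) and for FSD1 without wild-type white light 1, wild-type white light 2, pif457 white light 1, pif457 white light 2, wild-type 30 min 1, wild-type 30 min 2 or pif457 30 min 1 (adjusted p from 0.0612 to 0.185).

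In white light pif457 differed from wild type at 7 genes, 3 higher and 4 lower. The split is 8 higher and 12 lower with each library centred on its median gene and 125 higher and 107 lower among genes of mean TPM of at least 1. PIF7 (1.04±0.283 against 26.7±1.83 TPM, log2 change -3.77, adjusted p = 0.00774), PIF5 (3.37±0.933 against 37.9±6.73 TPM, log2 change -3.16) and QQS (AT3G30720, 26.7±1.86 against 150.5±1.89 TPM, log2 -2.45) were lower. MRD1 (AT1G53480, 36.6±1.72 against 0.645±0.233 TPM, log2 change 4.52, adjusted p = 0.00375) was higher (2 libraries each). PIF4 (11.6±0.431 against 39.8±10.3 TPM, adjusted p = 0.297), HFR1 (1.7±0.205 against 5.97±1.05 TPM) and ATHB2 (4.01±0.453 against 6.53±1.58 TPM) did not pass. Nor did PIL1 (log2 change -0.50), YUC8 (-0.97), IAA29 (-1.6), IAA19 (-0.60) and XTH15 (-1.27). By list, flavonoid genes lay higher (9 of 12 over the list alone, such as CHS at 236±41 against 100.3±27.2 TPM, adjusted p = 1.85e-12). So did photomorphogenesis regulators (adjusted p = 0.0247) and heat shock genes (adjusted p = 0.0262). SAUR genes lay lower (10 of 19 over the list alone, adjusted p = 2.47e-14). Touch (adjusted p = 4.48e-09), root markers (adjusted p = 3.44e-05), and ethylene genes lay lower (adjusted p = 4.14e-05). So did Aux/IAA and GH3 (adjusted p = 0.000155), shade-induced regulators (adjusted p = 0.000651), and HLH factors (adjusted p = 0.000716). Phytochromes and PIFs (0 raised and 2 lowered of 12, or 1 and 3 adjusted over the list alone, adjusted p = 0.000878), antenna (adjusted p = 0.000953), cell wall (adjusted p = 0.00121) and brassinosteroid genes (adjusted p = 0.00139) lay lower as well. All of these are lost (adjusted p from 0.466 to 0.701 with an estimated correlation). With only these 2 groups fitted the call on PIF5 ends. Calls are gained among genes of mean TPM of at least 1 for PIF4 (adjusted p = 6.49e-09), CHS (2.78e-08), IAA29 (4.6e-06), HFR1 (8.01e-05), XTH15 (0.00038) and YUC8 (0.0476), and for PIF4 (0.0128) and HFR1 (0.0146) with centring. The calls end for PIF7 without any 1 of the 4 libraries (adjusted p from 0.0631 to 0.126), PIF5 and QQS without wild-type white light 1, wild-type white light 2 or pif457 white light 1 (adjusted p from 0.0602 to 0.126) and for MRD1 without wild-type white light 2 (adjusted p = 0.0501). The count of 7 is 20 without wild-type replicate 1 and 19 and 28 without pif457 replicates 1 and 2.

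After 30 min of low R:FR the difference between pif457 and wild type was far wider. YUC9 (0.12±0.17 against 16.8±1.34 TPM, log2 change -4.0, adjusted p = 0.000528) and ATHB4 (5.05±1.65 against 82.1±7.01 TPM) were lower in pif457. So were YUC5 (0.17±0.0424 against 8.38±0.912 TPM) and ATHB2 (17.9±0.799 against 141±11.1 TPM, log2 change -2.91). MRD1 was higher (38.5±10.6 against 0.66±0.339 TPM, 2 libraries each). HFR1 (log2 change -2.05), PIL1 (-1.74), YUC8 (-2.18), IAA29 (-2.03), XTH15 (-1.76), PIF7 (-3.69), PIF5 (-2.83) and PIF4 (-1.47) were lower too. IAA19 (-0.94) did not pass. FSD1 (439.5±116 against 97.7±15 TPM) was higher. Among the largest differences were root genes, lower in pif457: the iron transporter gene IRT1 (AT4G19690, 1.69±0.983 against 31.6±13.8 TPM, log2 -3.59) and the Casparian strip gene CASP2 (AT3G11550, 0.78±0.0848 against 9.96±3.09 TPM, log2 -2.6).

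In all 1229 genes were lower and 51 higher in pif457 at 30 min, 757 and 22 by at least 2-fold. The split is 1934 lower and 433 higher after rRNA and organellar transcripts are removed. It is 1574 lower and 740 higher with each library centred on its median gene. The median of all genes above 5 TPM shifted by -0.179. Root markers moved with this difference: 0 raised and 12 lowered of 16, or 1 and 14 adjusted over the list alone, median -1.72 (adjusted p = 1.21e-09, adjusted p = 0.58 with an estimated correlation). Their mean log2 levels were 0.77 and 1.24 in pif457 against 2.73 and 2.46 in wild type. Shade-induced regulators (0 raised and 8 lowered of 12, or 0 and 8 adjusted over the list alone, adjusted p = 1.54e-08) and auxin biosynthesis (0 raised and 5 lowered of 11, or 0 and 6 adjusted over the list alone, adjusted p = 6.93e-05) lay lower. So did jasmonate genes (0 raised and 3 lowered of 15, or 0 and 10 adjusted over the list alone, adjusted p = 0.0143). Cell wall genes (0 raised and 4 lowered of 21, or 1 and 8 adjusted over the list alone, adjusted p = 0.0248) and ethylene genes (0 raised and 3 lowered of 15, or 0 and 7 adjusted over the list alone, adjusted p = 0.0108) lay lower. HLH factors (0 raised and 2 lowered of 8, or 0 and 3 adjusted over the list alone, adjusted p = 0.0428) and phytochromes and PIFs (0 raised and 4 lowered of 12, or 0 and 5 adjusted over the list alone, adjusted p = 0.0113) lay lower. Cytokinin genes (0 raised and 2 lowered of 16, or 0 and 3 adjusted over the list alone, adjusted p = 0.0196) and SAUR genes (0 raised and 2 lowered of 19, or 0 and 9 adjusted over the list alone, adjusted p = 0.0143) did too. Heat shock genes had 0 raised and 1 lowered of 6, or 0 and 3 adjusted over the list alone (adjusted p = 0.0113). All of these are lost (adjusted p from 0.466 to 0.701 with an estimated correlation). The count of 1280 is 36 and 390 without wild-type 30 min replicates 1 and 2. It is 42 and 8025 without pif457 30 min replicates 1 and 2. IAA19 passes among genes of mean TPM of at least 1 (adjusted p = 0.0109). The calls on YUC9, ATHB4, YUC5, ATHB2 and MRD1 hold in every alternative tried. They end for FSD1 and PIF7 without wild-type 30 min 1 (adjusted p from 0.0551 to 0.0586), PIF5, HFR1, YUC8 and CASP2 without wild-type 30 min 1 or pif457 30 min 1 (adjusted p from 0.0579 to 0.0992) and for PIF4, PIL1, IAA29, XTH15 and IRT1 without wild-type 30 min 1, wild-type 30 min 2 or pif457 30 min 1 (adjusted p from 0.0529 to 0.292).

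Raised genes are shared between the tables, which have no library in common. Of genes raised at 2 h in table I, 86 are raised at 30 min in table II (12.8 expected, odds ratio 9.69, adjusted p = 3.68e-46, Fisher's exact test). Of the same genes 7 are raised in wild type of table III (0.36 expected, odds ratio 27, adjusted p = 6.72e-08). Tables II and III share 11 genes raised at 30 min (1.14 expected, odds ratio 15.1, adjusted p = 1.16e-08). Lowered genes shared by tables I and II number 17 (2.05 expected, odds ratio 9.59, adjusted p = 9e-11). At an adjusted p under 0.01 they number 4 (0.13 expected, odds ratio 35.1).

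PIF7 binding events lie near many of these genes. In the list of PIF7-MYC under low R:FR against wild-type IgG (1052 events), the strongest event, on chromosome 5 at position 23359553, has AT5G57670 as its nearest gene, with the authors' strength of 1735. CKX5 (chromosome 1, 28319019, 19.8-fold), PHYB (chromosome 2, 8139647, 19.9-fold), the auxin influx carrier gene AUX1 (AT2G38120, chromosome 2, 15977428, 15.5-fold), FLP1 (chromosome 4, 15227987, 10.2-fold) and ATHB4 (chromosome 2, 18521583, 32.8-fold) are among the 10 strongest. A pair of events at 9444227 and 9443424 on chromosome 4, 31.3-fold and 17.9-fold, have ATHB2 as nearest gene but lie more than 3 kb from it. YUC8 (chromosome 4, 14192087, 11.5-fold) and XTH15 (chromosome 4, 8140135, 4.7-fold) have events in this list. In the list of 30 min low R:FR against white light (1408 events) an event lies inside ATHB2 (chromosome 4, 9450468, 2.8-fold). The direction of the list that pools the low R:FR and white light samples (998 events, here the pooled list) is left open, since its labels name the groups in 2 ways.

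Of the events 95.0%, 96.3% and 95.4% have a protein-coding gene within 3 kb, and 24.0%, 26.8% and 25.8% lie inside one. The lists overlap: 73.8% of IgG list events lie within 100 bp of a 30 min list event (2.68 events on average and at most 6 in 100 random placements). Of the 30 min list events 56.6% lie that near to an IgG list event and 55.8% to a pooled list event, and of the IgG list events 65.8% to a pooled list event. Of the pooled list events 69.8% and 77.6% lie that near to an event of the IgG and 30 min lists. The authors' caller reported a k-mer with the G-box core, which bHLH factors bind, at 62.5%, 69.9% and 79.7% of events, and with the PBE-box at 9.6%, 13.1% and 3.0%. It reported no k-mer at 0.5%, 1.0% and 11.4%. A sequence test was not run.

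Genes raised at 30 min in table II lie near events far more often than other genes. They are 226 of 739 genes near IgG list events (29.5 expected, odds ratio 13.8, adjusted p = 1.6e-139, Fisher's exact test). They are 284 of 1075 near 30 min list events (odds ratio 12.1, adjusted p = 2.39e-159) and 218 of 772 near pooled list events (odds ratio 12.1, adjusted p = 2.84e-126). Those raised at 2 h in table I do so too, with odds ratios of 11.7, 8.71 and 10.9 (7.76, 5.52 and 6.96 when every gene within 3 kb counts). Those raised in wild type of table III do so with 8.55, 7.09 and 8.19 (6, 7 and 6 of 27 genes), but within 1 kb the pooled list gives 4.57 (3 genes, adjusted p = 0.069). Lowered genes gave no such enrichment: near IgG list events the odds ratio is 0.606 (adjusted p = 0.656, 0.452 and adjusted p = 0.0394 when every gene within 3 kb counts) for table II and 1.34 (adjusted p = 0.656) for table I. Moving IgG list events by 5 to 20 kb takes the share of near genes that are raised at 30 min from 30.6% to between 5.3% and 13.5%. The test treats genes as independent, and whether neighbouring genes are was not tested.

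Genes raised at 30 min in table II were followed in table III. The 284 near a 30 min list event had mean log2 changes of 0.291 in wild type and -0.063 in pif457. The 650 others had -0.006 and -0.124. The median gene above 5 TPM moved by 0.051 and -0.174 (interaction -0.228), so the near genes' mean lay above it in both. The interaction was -0.354 near events and -0.118 elsewhere. Of the difference of -0.236, -0.141 is beyond the mean of permutations within strata of the table II response and of level (permutation p = 4e-05, adjusted p = 6e-05). The excess was -0.161 for the IgG list (permutation p = 1e-05, the smallest possible) and -0.14 for the pooled list (permutation p = 0.00021).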

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

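All tests of explanations in this part were chosen only after the result was seen. The response to 30 min of low R:FR differed between pif457 and wild type at 10 genes by the interaction term of the fit, with 2 libraries per group. Interactions on the log2 scale were -4.29 for ATHB4, -3.93 for YUC9 and -3.15 for YUC5 (adjusted p = 0.00883 each). AT3G41761 had 4.09 (adjusted p = 0.0315), with -0.87 in wild type and 3.22 in pif457, and FSD1 2.65 (adjusted p = 0.0327), with -0.91 and 1.75. MIR848 (AT5G13887) had -1.03 (adjusted p = 0.0319), being listed at 0 in 6 of the 8 libraries. AT2G17070 had -1.20 and AT1G67760 -1.17 (adjusted p = 0.0325 each), MYB54 (AT1G73410) -1.49 (adjusted p = 0.0375) and AT1G71000 -1.68 (adjusted p = 0.0394), none of them above 1.65 TPM in any library.

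Of the 1229 genes lower in pif457 than in wild type at 30 min, 3 accounts were tested. Scaling by a larger rRNA and organellar share in pif457 30 min replicate 1 is argued against as the sole cause. Removing those transcripts moves the median gene of this comparison by 0.103, and 1221 of the genes stay lowered (893 with median centring). That library has 17714 genes at 1 TPM or more, the fewest of the 29 libraries. Its other traits were not tested as a cause. Less root tissue in the pif457 30 min libraries was not told apart from lower root gene expression. The test used white light replicate 2 of table II, 1 library of another line with high root markers. There the genes lie higher by a median of 0.569 (at most 0.107 in 1000 random lists of like expression). Nearness to PIF7 events cannot be the whole cause, with an odds ratio of 1.61 (exact p = 0.000112). Of the 1199 protein-coding genes among them 7.2% are near an event, against 4.7% of all tested. An effect of the genotype in the plant stays open, untested.

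The genes raised at 10 min in the PIF7-MYC line were set against root tissue in the same way. Over all 1030 raised genes the median difference of white light replicate 2 is 0.18, where the 10 min change is 0.537, so that a share of root tissue and an early light response cannot be told apart for them. For the raised shade-induced regulators (ATHB2, ATHB4, HAT1 and PAR1) the same median is 0.08 against a change of 0.889. White light replicate 2 is 1 library and part of the white light mean that these genes were called against, so the 2 cannot be told apart for them either.

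Among genes raised at 30 min in the PIF7-MYC line, the interaction in table III is more negative near PIF7 events by -0.236, of which -0.141 is beyond permutation within strata (permutation p = 4e-05) and -0.096 is the mean of the permutations. The strata were of the response in the PIF7-MYC line and of level, not of the wild-type response of table III. Near events that response is higher by 0.297, no less than the interaction difference. A larger loss near events and a stronger wild-type response near events therefore cannot be told apart. Whether neighbouring genes are independent was not tested, and a bound gene need not be a regulated one.

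Groups of 3 libraries give 10 splits, too few for a share under 0.05. The real split gave the most genes in 1 of 10 each time: 500 at 2 h (highest other split 4), 180 after recovery against white light (3), 280 against 2 h (6), 955 at 5 min (2), 1582 at 10 min (1) and 1188 at 30 min (99).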

How the results depend on the processing

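Alternatives were set before the data were examined, except the rRNA and organelle removal and the median centring, chosen after seeing the data. Of 153 named values past the threshold 114 stay past it in every alternative and 137 in every alternative that keeps all libraries. Of 232 named values 0 changed sign with a call in the main fit or the alternative. Changes of sign without a call were not counted. Named values short of the threshold pass it in 23 cases with 1 TPM in 2 libraries, 22 with a mean TPM of at least 1, 13 with centring, 4 with a pseudocount of 0.1, 3 with rRNA and organellar genes removed, 2 with only the groups compared and 9 on leaving out 1 library. The low-TPM filters leave each log2 change as it was, so gains there come from the variance shared among genes and from the genes tested. The planned count-based normalization, test and filter were not run, as the tables hold TPM, and depth is unknown. Where leaving out a library leaves 1 in a group, that library is assumed to vary like the others.

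Counts of changed genes moved as follows, and the cause was not tested, except that a 2-fold threshold can only take genes away. With a 2-fold threshold they are 267 at 2 h, 95 after recovery, 75, 137 and 169 at 5, 10 and 30 min, 18 in wild type of table III and 779 for pif457 against wild type at 30 min. With a pseudocount of 0.1 they are 13 in wild type and 21 in pif457 at 30 min, 5 for the interaction and 12 for pif457 in white light. Among genes of mean TPM of at least 1 they are 361 after recovery, 619 and 593 in wild type and pif457 at 30 min, 806 for the interaction and 232 for pif457 in white light, and with 1 TPM in 2 libraries 352, 699, 593, 867 and 214, and 1953 for pif457 against wild type at 30 min. A replicate block gives 80 after recovery, 556 and 920 at 5 and 10 min and 19 in wild type of table III. Fitting only the groups compared gives 296 at 2 h, 90 after recovery, 556, 129 and 423 at 5, 10 and 30 min, 3 and 141 in wild type and pif457 at 30 min, 3 for pif457 in white light and 2059 at 30 min. Removing rRNA and organellar genes gives 328 after recovery, 54 and 20 in wild type and pif457 at 30 min and 2367 between them, and centring gives 312, 379, 167 and 2314, with 192 for the interaction and 20 for pif457 in white light.

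Leaving out 1 library gives 262 to 493 at 2 h, 51 to 165 after recovery, 157 to 191 for recovery against 2 h, 218 to 804, 106 to 3542 and 497 to 1548 at 5, 10 and 30 min. In table III it gives 19 to 35 in wild type, 15 to 5511 in pif457, 7 to 3145 for the interaction, 9 to 28 for pif457 in white light and 36 to 8025 at 30 min.

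Lists past camera with an estimated correlation number 4 of 14 at 2 h, 1 of 8 after recovery, 0 of 4 at 5 min, 0 of 8 at 10 min and 2 of 8 at 30 min. In table III they number 0 in all 5 comparisons, and with fry 2 in wild type, 0 in pif457, 1 for the interaction, 0 for pif457 in white light and 2 at 30 min. The overlap of lowered genes of tables I and II is 0 with a 2-fold threshold, where 0.06 are expected by the fewer genes called. IgG list events shared with the 30 min list are 77.8% at 200 bp and 82.1% above the median strength, and pooled list events shared with the IgG list 65.0% at 50 bp and 86.0%, with the 30 min list 73.4% and 85.0%. Lowered genes of table II near IgG list events have an odds ratio of 0.452 (adjusted p = 0.0394) when every gene within 3 kb counts, and raised genes of wild type in table III near pooled list events 4.57 (adjusted p = 0.069) within 1 kb. Above the median strength the G-box k-mer stands at 74.5%, 76.7% and 77.8% of IgG list, 30 min list and pooled list events. The PBE-box stands at 7.0%, 11.6% and 3.6%, and no k-mer was reported at 0.6%, 1.3% and 14.8%.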
